A study of Homo sapiens with 28 samples.

How the data were processed

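RNA of human stem cell derived cardiomyocytes was measured in 20 bulk and 8 single-cell libraries. Bulk totals ran from 5698613 to 24742768 counts and single-cell totals from 2335023 to 11042764 UMIs. The bulk table holds a raw read count per Ensembl gene and library, as deposited by the authors, for 63677 gene identifiers and 20 libraries. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.9 and HTSeq were used with the builds hg19 and GRCh37, and their roles, order and strand setting are not given in the sources used here. Without a stated strand setting, antisense genes and overlapping genes are reported as uncertain, as are pseudogenes and near-identical copies. The single-cell table holds the natural log of 1 plus 10000 times a gene's UMIs over the cell's UMIs, as deposited by the authors, although it was planned for as counts. Per the submitters' processing notes Cell Ranger and Seurat were used, and their versions are not given in the sources used here. A table of cells, as deposited, gives each cell's library, its count of UMIs and of genes, and the fraction of its UMIs from mitochondrial genes.

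The log was undone with each cell's UMI total, and 100% of values came back whole within 0.001, with sums equal to the deposited totals in 2435 of 2435 cells. The lowest cell total was 3029 UMIs and the highest mitochondrial share 39.9%, and no cell was removed here. Of the bulk identifiers 52181 were matched to a symbol through a table of gene names, as were 97.3% of those with 100 counts or more in all. Of the 33694 single-cell gene names 20628 were matched to 1 bulk identifier. No coordinates are given, and every table column was matched to a sample.

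Bulk libraries were grouped by the labels, and code series by the start of the column names, a technical split that the labels do not explain. Genes were kept by edgeR's filterByExpr and tested with edgeR 4.0.16 (R 4.3.3), with TMM factors and the quasi-likelihood test, Benjamini-Hochberg adjusted at 0.05. MiMac against EV was fitted over 11 libraries with a term for the code series, and HOPX_OE against its control over 4 libraries. The SE of a log2 fold change is its size over the square root of F. Values in CPM use the TMM factors of the libraries in that fit, and lookups across all 20 libraries use factors over all 20. Lists were tested with camera of limma 3.58.1 at its preset correlation, again with an estimated correlation, and with fry. Simulated data with 200 changed genes were tested first. Of 4-fold and 2-fold changes 68% and 3% were recovered over the 11 MiMac and EV libraries, 100% and 96% over the 6, and 100% and 90% for HOPX_OE, with 4.1%, 8.4% and 4.5% false calls.

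Single bulk libraries were compared with the EV libraries of their code series by log2 CPM with a prior count of 2. Single-cell values are UMIs summed per library over all cells, as CPM of the library total. The ratio has an exact conditional binomial interval at 95% and a level an exact Poisson one. On data simulated from the same Poisson counting model 93 to 99% of ratio intervals held the true change. That checks the calculation only, since variation between cells was not simulated. UMIs remove amplification copies, but bulk counts do not, so intervals and floors cover counting error only. For HOPX_OE genes with a bulk library at 3 counts or fewer the same interval was taken on summed counts. The floor is 3 counts, per library, which is 0.272 to 1.28 CPM in the single-cell libraries. A list's median was placed among 10000 random lists of the same size matched on expression, as a description of those libraries. Cells were clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6) and named from marker lists. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. Comparisons share the EV, wild type and mutant single-cell libraries, so no overlap or correlation between them is given.

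The lists, tests, markers, rule for named genes and first set of alternatives were fixed before the data were examined. There are 33 lists: fatty acid beta-oxidation, fatty acid uptake and PPAR targets, cardiolipin synthesis and remodelling, oxidative phosphorylation, mitochondrially encoded transcripts, the citrate cycle, glycolysis, uncoupling and carriers, sarcomere genes higher in mature cardiomyocytes, fetal cardiomyocyte genes, ion channels and calcium handling, the cell cycle, cell cycle inhibitors with stress-induced genes (the cell cycle inhibitor list), targets of let-7, miR-122 and miR-200, cholesterol synthesis, fatty acid synthesis, the unfolded protein and amino acid stress response, oxidative stress, heat shock, hypoxia, interferon, extracellular matrix, cardiac transcription factors, and markers of fibroblast, epicardial, endothelial, smooth muscle, endoderm, pluripotent, epithelial and neural cells. The cell cycle inhibitor list was fixed under the name cell cycle inhibitors and p53 targets, and holds p53 targets such as MDM2 and BBC3. Some genes stand in more than 1 list.

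The bulk genes named are HOPX and HADHA, the 8 largest changes each way past the threshold at an average log2 CPM of 2 or more (for MiMac with the same sign in both code series), and up to 3 members of each list with the smallest adjusted p. For single bulk libraries they are the 3 highest and 3 lowest log2 ratios at an average log2 CPM of 3 or more outside the range of the 8 EV libraries. For single cells they are HOPX, HADHA, the 8 or 4 largest ratios each way at 100 UMIs and 20 CPM or more, and up to 2 members of each list with a log2 ratio beyond 0.5. Genes of the sex chromosomes used to tell sex, ribosomal protein genes and clone names were left out. Where a comparison had over 30 such genes, those that stand for their list are named. Some genes that the rule picks are not reported here. The MiMac rule was applied to the 6-library fit, a choice made after the 11-library fit called 0 genes.

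The alternatives of that first set were RLE size factors, DESeq2 1.42.0, no filter, a replicate block, all 20 libraries, a log2 fold limit of 1, no series term, the 6 or 4 libraries of shared series (8 for HOPX_OE), other list tests, leaving out each library in turn, and a threshold of 0.1 for the overlap. For single libraries they were all 8 EV libraries as control and a prior count of 0.5, and for single cells the cardiomyocyte class alone, cells of 2000 UMIs or more (which left out 0 cells), totals without mitochondrial and ribosomal protein genes, TMM factors and equal weight for cells. Added after seeing the data were fits without EV 2 and 3 or EV 4 and 5, those pairs as lone controls, cells of 50000 UMIs or fewer, cells outside the dividing cluster, the cardiomyocyte class with the unnamed clusters and the use of the 6-library calls. No doublet caller was run.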

Results

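RNA was measured in cardiomyocytes grown from human stem cells, in 20 bulk libraries and in 8 single-cell libraries. The labels name the embryonic line RUES2 and the induced line WTC, both established lines, and a lactate step that left 75 to 80% cardiomyocytes, but not which line each library came from. The bulk libraries held 8 of an empty vector (EV) control, 3 of MiMac and 2 each of HOPX_OE and its negative control. MiMac is a cocktail of 4 microRNA changes, overexpression of let-7i and miR-452 with knockout of miR-122 and miR-200a, made to advance cardiomyocyte maturation. Single bulk libraries carried miR-208b, miR-378e or miR-452 overexpression or miR-205 or miR-122 knockout. Bulk totals ran from 5698613 counts (EV 6) to 24742768 (MiMac 3). The column codes of the bulk table fall into 4 series, called A to D here. Series A held EV 1 and miR-208b, series B EV 2 to 5 and the other single libraries, series C MiMac 1 and EV 6, and series D EV 7 and 8, MiMac 2 and 3 and both HOPX groups. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

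The first comparison asks what the full cocktail did to the bulk transcriptome. As a check of the labels, MIRLET7I, the gene of let-7i, stood at 1.02, 2.58 and 1.92 CPM (counts scaled to the total of the library) in MiMac 1 to 3 and at no more than 0.132 CPM in every EV library. Mature microRNAs were not measured by these libraries, and MIRLET7I was singled out after its values were seen. Over all 11 libraries with a term for the code series, edgeR called 0 of 16653 genes. At an unadjusted p under 0.05 it listed 410, and DESeq2 called 9, 8 up and 1 down. Series A and B hold no MiMac library, so with this term EV 2 to 5 entered mainly through the estimate of the spread. Their biological coefficient of variation was 44.3%, against 9.98% within EV 2 and 3 and 20.2% within EV 4 and 5. The count of 0 therefore does not show that MiMac changed no gene. The 6 libraries of series C and D, which hold both groups, were an alternative planned in advance for the gene count, and edgeR called 385 of 16984 genes there, 187 up and 198 down. The genes below come from this smaller set of libraries, a use of it chosen after the 11-library count was seen. MiMac and EV each have n = 3 in it.

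Among genes that rose, NRAP, a scaffold of growing myofibrils, had the largest log2 fold change at 2.02 ± 0.32 (SE; edgeR adjusted p = 0.0142), with 22.4 ± 0.515 CPM (SD) in MiMac and 7.77 ± 7.19 in EV. NUPR1, a stress-induced regulator, rose by 1.47 ± 0.21, and ETV5, a transcription factor, by 1.22 ± 0.19. TFPI2, AFAP1L2, RGS4, MAP2 and PSMB8 rose by 1.54, 1.5, 1.44, 1.41 and 1.31. SLC28A3, a nucleoside transporter, fell by 1.29 ± 0.22. C1orf105 fell by 1.39, MGAT4C by 1.23, MYO5C by 1.2 and MIR133A1HG, a host transcript of a muscle microRNA, by 1.17. PPP1R3A, a glycogen-targeting phosphatase subunit, fell by 1.15 ± 0.22 (16.4 against 36.2 CPM) and ANKRD12 by 1.11. These changes pool series C and D, which were not always alike. PPP1R3A stood at 15.7 CPM in MiMac 1 against 16.7 in EV 6. In series D it stood at 14.4 and 19 against 47.2 and 44.6. NRAP stood at 22.6 against 16.1 in C, and at 22.7 and 21.8 against 3.62 in both EV libraries of D. ETV5 stood at 22.9 against 18.1 in C. SLC28A3 fell in both, to 2.21 from 7.04 in C and to 3.28 and 3.59 from 9.36 and 6.46 in D. ACTG1P14 at 1.22 and FAR2P1 at -1.16 are pseudogenes whose reads cannot be parted from their parent genes here, so they remain uncertain. HOPX had a log2 fold change of 0.29 ± 0.10 (edgeR adjusted p = 0.147) and HADHA, the trifunctional protein subunit of long-chain fatty acid oxidation, 0.07 ± 0.09 (adjusted p = 0.709).

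In the interferon response list 6 of 25 measured genes rose and 0 fell, or 14 and 0 adjusted over the list alone, among them PSMB8 (1.31), an immunoproteasome subunit, and HLA-B (1.13 ± 0.15) and HLA-C (0.95), which present peptides to T cells. In the fetal cardiomyocyte list 4 of 18 rose, or 6 with 1 that fell adjusted over the list alone. They include the natriuretic peptides NPPB (1.07 ± 0.13; 347 against 187 CPM) and NPPA (0.67) and skeletal actin ACTA1 (1.06; 269 against 139 CPM). The sarcomere list also had 4 of 28 that rose (7 up and 2 down adjusted over the list alone), among them NRAP, the intermediate filament gene DES (1.09 ± 0.13) and CSRP3 (0.51). Of the unfolded protein and amino acid stress list, 4 of 30 rose and 1 fell (11 up and 1 down adjusted over the list alone), with CHAC1 at 0.77, TRIB3 at 0.73 and SHMT2 at 0.58. SQSTM1 (0.67) rose in the oxidative stress list. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 0.56 (2205 against 1474 CPM) and PHLDA3 by 0.47 in the cell cycle inhibitor list. TNC (0.71) and TIMP1 (0.59) rose in the extracellular matrix list, KRT8 (0.47) and KRT18 (0.37) among epithelial markers, TAGLN (0.88) and CNN1 (0.55) among smooth muscle markers, and ENO1 (0.54) and PGK1 (0.48) in glycolysis.

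Of 44 measured cell cycle genes 2 fell and 0 rose, or 8 and 0 adjusted over the list alone. These were CENPF (-1.05 ± 0.23), which acts at kinetochores, and NUSAP1 (-1.07 ± 0.18), a spindle protein. Of 48 let-7 targets 5 fell, or 9 with 2 that rose adjusted over the list alone, including the chromatin gene ARID3B (-1.05 ± 0.19), FIGN (-1.04 ± 0.15; 21.5 against 42.9 CPM) and SMARCAD1 (-0.92 ± 0.14). Of 34 ion channel and calcium genes 3 fell, namely CACNA1G (-0.60), KCNIP2 (-0.58) and TRDN (-0.53), a list whose set test was not called (camera adjusted p = 0.16). PDK1 fell by 0.62 while EGLN3 and BHLHE40 rose by 0.88 and 0.50 in the hypoxia list, which was not called either (adjusted p = 0.942; its median was negative and its test pointed up). STARD4 (-0.60), ACADM (-0.49), NDUFA5 (-0.60) and IRX4 (-0.45) each fell in a list that was not called. KLF6 (0.63), STAT4 (0.70) and HSPB1 (0.58) rose.

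Camera with its preset correlation called 13 of the 33 lists over the 6 libraries, 10 up and 3 down. The lowest adjusted p-values were 4.05e-11 for interferon, 1.46e-09 for the cell cycle and 4.48e-08 for fetal genes. All 13 calls were lost when the correlation was estimated, with adjusted p = 0.403 with an estimated correlation for these 3 lists. Mitochondrially encoded transcripts were called down (13 of 13 lower, median -0.20, camera adjusted p = 0.00298; adjusted p = 0.65 with an estimated correlation), though 0 of the 13 genes were called. Over 11 libraries that list was not called (adjusted p = 0.15). Over 11 libraries camera called 5 lists, cell cycle down (39 of 45 members lower), interferon up (26 of 29 higher), fetal genes up (16 of 18), the unfolded protein response up (23 of 30) and let-7 targets down (33 of 48 lower). Without a term for the code series the unfolded protein call turned to down (adjusted p = 0.588), and with an estimated correlation the 5 lists had adjusted p = 0.374, 0.655, 0.488, 0.655 and 0.752. Leaving out MiMac 1 or EV 6 raised these 5 calls to 9 and 8. Fatty acid beta-oxidation (adjusted p = 0.615, ACADM the only gene called), cardiolipin synthesis (0.615) and oxidative phosphorylation (0.492) were not called over 6 libraries.

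The 385 calls rested on which libraries entered. Without EV 7, EV 8, MiMac 2 or MiMac 3 edgeR called 2, 1, 5 and 1 genes, and without MiMac 1 or EV 6, which leaves the test to series D, it called 2406 and 2402. In the 11-library fit without a term for the code series, AFAP1L2, RGS4, PSMB8, TAGLN, TRIB3, TNC, ENO1 and PGK1 had negative log2 fold changes and KCNIP2 a positive one. The DESeq2 count was 755, of which 375 were shared with edgeR. Within series D alone 2406 genes were called, and the log2 differences of series C and D correlated at 0.0377 across genes, which are not independent replicates. Of 2366 genes called in series D and measured in C, 59.9% had the same sign in C, against 53.6% in random draws (95% range 51.6 to 55.3). Among the EV libraries themselves, CDKN1A stood at 43.4 and 44.4 CPM in EV 2 and 3 and at 3104 and 2366 in EV 4 and 5.

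**Figure D1:**
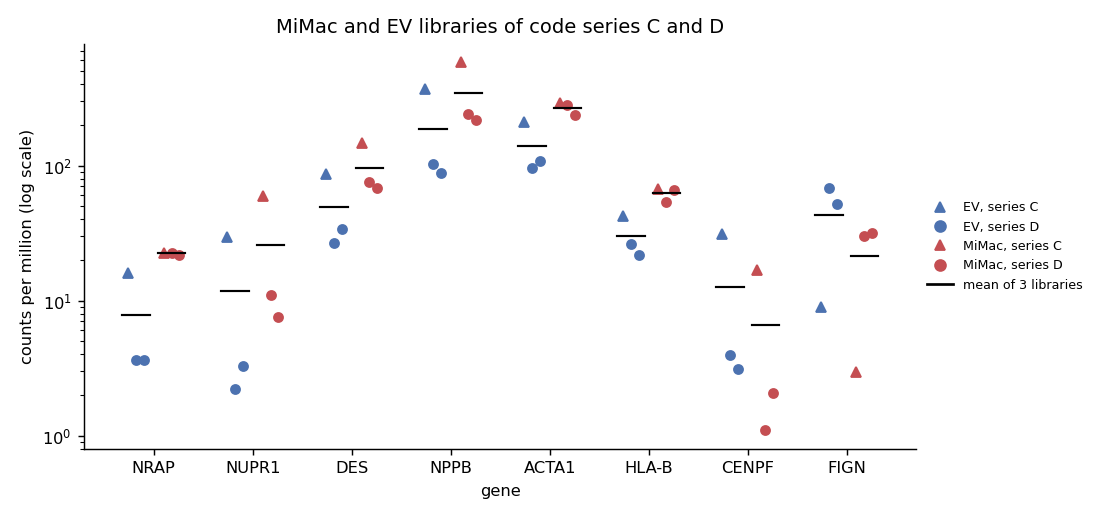
CPM (log axis) of 8 genes in the 3 MiMac and 3 EV libraries of code series C and D, with points for libraries, marker shapes for series and bars for group means. NPPB averaged 347 CPM in MiMac and 187 in EV, and FIGN 21.5 and 42.9.

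The second bulk comparison set the 2 libraries labelled HOPX_OE against their 2 negative controls. HOPX, the homeodomain gene that the label says was overexpressed, was not higher in the libraries labelled HOPX_OE, at 13.2 ± 1.0 CPM against 17.1 ± 1.4 in the controls (log2 fold change -0.38 ± 0.15, edgeR adjusted p = 0.128). With factors over all 20 libraries HOPX was lower in all 4 of them than in EV 7 and 8 of the same series (34.4 and 41.5 CPM). A vector with another sequence than the annotated gene would not be counted, and the labels used here do not settle this. EdgeR called 3290 of 18793 genes, 1679 up and 1611 down. CAT, the peroxisomal catalase, fell (edgeR adjusted p = 5.23e-05), from 870 and 882 counts in the controls to 0 and 2. The log2 ratio of its summed counts was -9.77 (exact interval -12.82 to -7.91, counting error only). H19, an imprinted long non-coding RNA, fell by 8.27 ± 0.22, from 7900 to 25.5 CPM. DLL1, a Notch ligand, fell by 5.95, TSPYL5 by 5.72 (to 4 and 3 counts, interval -7.10 to -4.72), the antisense YPEL3-DT (uncertain without strand) by 5.12 and TXNRD2, mitochondrial thioredoxin reductase, by 3.14. For DLL1 and YPEL3-DT it was the controls that stood apart (17.4 and 16.9, and 14.5 and 17.4 CPM with factors over all 20 libraries), since the 16 other bulk libraries lay at 1.06 CPM or less and 1.84 or less. SYT4, a synaptotagmin, had 0 counts in both controls and 9.41 CPM in the libraries labelled HOPX_OE, at least 75.7-fold higher against a floor of 3 counts per library. ITLN1, an intelectin of mesothelium, rose by 4.91 ± 0.26 (17.9 to 536 CPM), SCNN1G by 4.70 ± 0.18, NPHS1 by 4.58, ISLR by 4.17, EMCN by 4.12 (from 4 and 3 counts, interval 3.08 to 5.51), and both RAB37 and SIM1 by 4.09. HADHA had a log2 fold change of 0.00 (adjusted p = 0.998).

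Epicardial and fibroblast genes rose in the libraries labelled HOPX_OE, as did some endothelial markers at low levels. Of 10 epicardial or mesothelial markers 8 rose and 1 fell (the same adjusted over the list alone), with TCF21 at 2.91, the retinoic acid enzyme ALDH1A2 at 1.73 (274 to 905 CPM) and TBX18 at 1.09. Of 11 fibroblast markers 10 rose, all 11 adjusted over the list alone, with the collagen COL1A2 at 1.26 ± 0.17 (1031 to 2477 CPM), PDGFRA at 1.39 and POSTN at 1.05. Of 37 matrix genes 16 rose and 3 fell (19 and 7 adjusted over the list alone), led by COL6A3 (2.86 ± 0.23) and MMP2 (1.59). Of 7 endothelial markers 4 rose, including EMCN, PLVAP and ERG, which reached 2.60, 3.08 and 3.83 CPM, and 3 were lower without a call. PDIA4 (0.78), CEBPB (0.88) and PSAT1 (0.89) were among 9 of 29 genes of the unfolded protein response that rose, with 1 that fell (11 and 3 adjusted over the list alone). ZFP42 (2.09, to 2.94 CPM) was among 3 of 6 pluripotency markers that rose (5 and 1 that fell adjusted over the list alone).

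Cardiomyocyte genes fell in the same libraries, as did smooth muscle markers. Of 28 sarcomere genes 20 fell and 4 rose (20 and 5 adjusted over the list alone), with TNNI3, cardiac troponin I, at -1.83, MYOM2 at -1.78, COX6A2 at -1.72 and MYOM1 at -1.33 (609 to 242 CPM). Of 34 ion channel and calcium genes 18 fell and 3 rose (21 and 4 adjusted over the list alone). CASQ2, the calcium store protein of the sarcoplasmic reticulum, fell by 1.49, while CACNA1H rose by 1.56. In the fetal list 9 of 19 fell and 2 rose (10 and 2 adjusted over the list alone), among them NPPB (-3.21 ± 0.14; 164 to 17.8 CPM), NPPA (-2.5 ± 0.20) and ACTA1 (-2.24). MYOCD (-1.36), a coactivator of muscle genes, was among 13 of 30 cardiac transcription factors that fell, with 2 that rose (17 and 3 adjusted over the list alone). Of 45 cell cycle genes 16 fell and 2 rose (23 and 2 adjusted over the list alone), including ANLN (-1.10), CCNE1 (-0.95) and BUB1 (-0.94). Of 26 glycolysis genes 8 fell (11 adjusted over the list alone), with ALDOC at -1.37 and PKM at -0.92. In the citrate cycle 6 of 24 fell, with IDH3A at -1.23, and in fatty acid uptake 4 of 20, with the coactivator PPARGC1A at -1.40, the same numbers adjusted over each list alone. LMOD1 (-0.90), CNN1 (-0.90) and ACTA2 (-0.68) were 3 of 7 smooth muscle markers that fell (4 adjusted over the list alone), with 6 of 7 lower.

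Camera called 15 lists, 6 up and 9 down, namely those just described, with adjusted p-values from 1.48e-13 (epicardial markers), 3.49e-10 (fibroblast markers) and 2.95e-09 (sarcomere) to 0.0432 (fatty acid uptake). No call held with an estimated correlation, where the epicardial and fibroblast lists had adjusted p = 0.468 with an estimated correlation and the lowest value was no smaller. The rotation test fry called 5, the epicardial, endothelial, fibroblast, sarcomere and smooth muscle lists, with adjusted p between 0.00983 and 0.0451. It tests a list against no change, a different question from that of camera, which tests a list against the other genes. Not called were beta-oxidation (5 of 26 fell, with ACADL at -1.79; adjusted p = 0.173), oxidative phosphorylation (4 of 52 fell; 0.523; median positive and mean negative), cardiolipin synthesis (1 of 16 rose and 5 fell; 0.986; median positive and test down) and mitochondrially encoded transcripts (0 of 13; 0.485). The cell cycle inhibitor list (4 of 25 rose and 7 fell, CDKN1A at -1.89 and CDKN1C at 1.76; 0.445), the uncoupling and carrier list (2 of 12 each way; 0.903) and hypoxia (3 rose, 4 fell, ADM at -2.01; 0.275) were not called. Nor were let-7 targets (8 of 48 rose, with IGDCC3 at 2.76, and 5 fell; 0.795; median negative and mean positive), miR-122 targets (2 rose, 4 fell, GYS1 at -0.97; 0.308) and miR-200 targets (8 of 42 rose, 5 fell; 0.903; median negative and mean positive). The same held for cholesterol synthesis (1 rose, 2 fell; 0.485), fatty acid synthesis (1 of 16 fell; 0.308), oxidative stress (4 of 29 fell, CAT, TXNRD2 and GPX3 among them; 0.0693; median positive and mean negative), heat shock (1 rose, 4 fell; 0.191) and interferon (1 of 26 rose, 3 fell; 0.207). Epithelial markers (3 of 9 rose, among them CDH1 at 1.53, KRT19 at 1.25 and PODXL at 1.00, and 2 fell; 0.0754), endoderm markers (2 of 5 rose, 1 fell; 0.443) and neural markers (1 of 7 fell; 0.903; median negative and mean positive) complete the 33.

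The count of 3290 moved with the libraries and settings. Without negative control 1 or 2 it was 1322 and 1482, and without HOPX_OE 1 or 2 it was 6368 and 6089. Each of these fits leaves 1 library in an arm, assumed to vary like the other pair. The controls varied less (4.41%, biological coefficient of variation) than the libraries labelled HOPX_OE (17.2%), so the pair that was left set the way the count moved. With no filter on low counts edgeR called 159 genes and with the spread pooled over all 20 libraries 257, while DESeq2 called 3089.

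**Figure D2:**
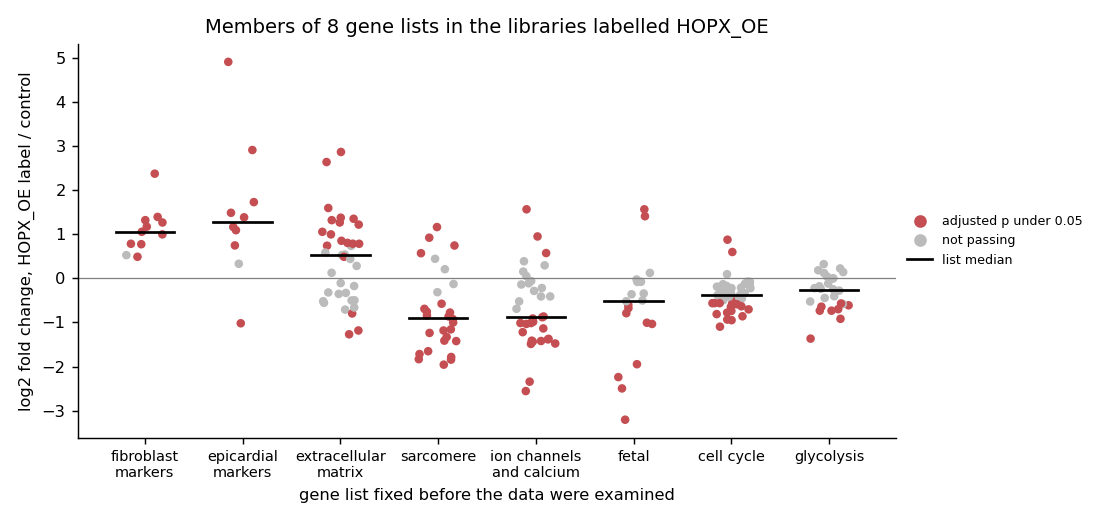
Log2 fold change of the libraries labelled HOPX_OE against their negative controls (n = 2 each) for the measured members of 8 gene lists, 1 point per gene, red where the adjusted p was under 0.05, with a bar at the median. The fibroblast and epicardial markers lie mostly above 0, where 10 of 11 and 8 of 10 rose, and 20 of 28 sarcomere genes fell.

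The bulk comparisons share no library, and their calls were set side by side. Because MiMac had 0 calls over 11 libraries, the planned overlap was 0, and the 385 calls of the 6 libraries were used instead, a choice made after seeing the data. Among 16723 genes tested in both, 37 rose in both where 15.2 are expected from independent lists (odds ratio 2.85, Fisher's exact p = 4.24e-07), and 43 fell in both where 18 are expected (2.83, exact p = 5.60e-08). A further 46 were called in opposite directions, where 33 are expected. Of these 35 were up with MiMac and down in the libraries labelled HOPX_OE (16.9 expected, odds ratio 2.35, exact p = 2.84e-05), among them NPPB, NPPA, ACTA1 and CDKN1A, and 11 the other way (16.1 expected, exact p = 0.237). The excess over independent lists was thus not limited to shared directions. The exact tests take genes as independent, which genes expressed together are not, so their p-values do not measure the spread between libraries. The log2 fold changes correlated at 0.0519 across all genes.

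Each remaining microRNA had 1 bulk library, so its values have no replicate check and no p-value. They were set against the EV library or libraries of the same code series. With miR-208b overexpression, ABCA1, a cholesterol exporter, was higher than in EV 1 (140 against 49.9 CPM, log2 ratio 1.49), as was ABCG1 (0.98). DCN (-2.32), a matrix proteoglycan, and complement C3 (-2.01) were lower. The cholesterol synthesis list had a median log2 ratio of -0.89, at percentile 0 of random lists, and the cell cycle list 0.84, at percentile 100. Markers of fibroblasts (-1.22, percentile 0) and smooth muscle (-0.36, percentile 0.2) and matrix genes (-0.53, percentile 0) were lower in the same library. With miR-378e overexpression COL6A3 (4.31), TBX18 (3.38) and LRP2 (3.22) were higher and CDKN1A (-4.36), ISG15 (-2.92) and ventricular light chain MYL2 (-2.60) lower than the log mean of EV 2 to 5. With miR-205 knockout COL6A3 (4.52), PIEZO2 (2.96) and TNC (2.85) were higher and CDKN1A (-4.27), EDA2R (-2.96) and MYL3 (-2.30) lower. In both libraries the oxidative phosphorylation list was low, with medians of -1.11 and -1.35 at percentile 0. In the same libraries fibroblast markers were at 1.21 and 1.61, matrix genes at 0.85 and 1.19 (all at percentile 100) and epicardial markers at 1.84 and 0.97 (percentile 100 and 99.7). These ratios depend on which EV libraries serve as control. On the first principal component of the bulk libraries miR-378e lay at 55.4 and miR-205 knockout at 47.8. EV 2 and 3, at 21.3 and 31.55, lay nearer to both than EV 4 and 5, at -84.97 and -74.25. For these libraries the ratios against EV 2 and 3 are thus those against the more similar controls. Against EV 2 and 3 oxidative phosphorylation was at -0.32 and -0.56, fibroblast markers at -0.13 and 0.49, matrix genes at 0.02 and 0.36 and epicardial markers at 0.96 and -0.14. Against EV 4 and 5 they were at -1.92 and -2.11, 2.06 and 2.71, 1.64 and 1.93, and 3.09 and 2.26. For COL6A3 in the miR-378e library the log2 ratio was 0.29 against EV 2 and 3 and 8.33 against EV 4 and 5, and for CDKN1A -1.39 and -7.33. In the miR-205 knockout library PIEZO2 was at 0.66 and 5.25, TNC at 0.56 and 5.14 and EDA2R at -0.88 and -5.03. With miR-452 overexpression IFI6, an interferon-induced gene, was at 834 CPM (log2 ratio 2.82), FREM2 (1.59) and DDX60 (1.58) were higher, and MZT2B (-1.74), UXT (-1.45) and UBE2S (-1.30) lower. Against EV 2 and 3 and EV 4 and 5 in turn, IFI6 was at 4.03 and 1.62, DDX60 at 0.75 and 2.41, MZT2B at -1.07 and -2.42 and UXT at -0.63 and -2.27. The interferon list had a median of 0.67, at percentile 100, and was above 0 against either pair of EV libraries (1.02 and 0.56). With miR-122 knockout SERPINI1 (1.31), MARCHF11 (1.24) and RRAD (1.17) were higher, PTGIS (-2.66), LAMA3 (-2.55) and PIEZO2 (-2.44) lower, the interferon list at -1.01 (percentile 0), and the miR-122 targets near 0 (0.10, percentile 63.4). Against EV 2 and 3 and EV 4 and 5 in turn, MARCHF11 was at 2.41 and 0.07, RRAD at 2.19 and 0.16, PTGIS at -4.57 and -0.74 and PIEZO2 at -4.74 and -0.14, while SERPINI1 and LAMA3 moved less (1.45 and 1.17, -3.13 and -1.96). The sarcomere list had medians of 0.25 with miR-208b, -1.07 with miR-378e, -1.20 with miR-205 knockout, -0.36 with miR-452 and 0.58 with miR-122 knockout. Fibroblast markers were at -1.22, 1.21, 1.61, -0.16 and -1.37 in the same order, and epicardial markers at -0.68 with miR-452 and -1.24 with miR-122 knockout. For miR-452 the sarcomere list was at 0.56 against EV 2 and 3, where fibroblast markers were at -1.24, and at -0.93 against EV 4 and 5, where they were at 1.00. For miR-122 knockout the sarcomere list was at 1.31 and -0.03 and the fibroblast markers at -2.57 and -0.32. On the first principal component miR-122 knockout (-70.99) lay by EV 4 and 5, and miR-452 (-12.2) between the pairs.

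The single-cell libraries covered EV, MiMac, let-7 with miR-452, miR-122 with miR-200, and 4 libraries of MiMac cells given fatty acids, wild type or HADHA mutant, each without and with SS-31. SS-31 (elamipretide) is a peptide that binds cardiolipin, the lipid of the inner mitochondrial membrane. They held 2435 cells, from 115 (wild type with fatty acid) to 865 (mutant with SS-31), and 2335023 to 11042764 molecules (UMIs) per library, with median UMIs per cell of 24229.5 in EV and 10061 in the mutant with SS-31. Each condition has 1 library, so no test between conditions was run. Values are UMIs summed over the cells of a library, as CPM, and 95% intervals cover counting error only. No doublet caller was run, and 77 cells held over 50000 UMIs.

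Cells fell into 7 clusters, of which 3 (clusters 0, 1 and 5) were cardiomyocyte-like, 1 fibroblast or stromal-like, 1 dividing-like and 2 unnamed. The cardiomyocyte class took 75.0% of EV cells (67.1 to 81.8, exact binomial interval), 64.3% in MiMac, 78.2% with let-7 and miR-452 and 70.8% with miR-122 and miR-200. It took 53.9% of wild type cells with fatty acid (44.4 to 63.2) and 70.1% of mutant cells (65.7 to 74.3). Of the wild type cells of the class 37 lay in cluster 1 and 25 in cluster 0, and of the mutant cells 270 lay in cluster 5, 58.4% of all cells of that library, and 53 in cluster 0. Cluster 1 took 32.2 to 59% of cells in the libraries without the mutation, against 0.216% in the mutant and 0.462% in the mutant with SS-31. Cluster 5 took 58.4 and 57.2% of the mutant libraries and 1.41% or less of each other library. Clusters 1 and 5 thus part the mutant libraries from the others, and may not be types of cell. Cluster 2, led by HHIP, CASQ2, NPPB and ANKRD1, stayed unnamed because MYH11, a smooth muscle marker, stood in its top 10. In 50% or more of its cells 19 cardiomyocyte markers were found, as in cluster 1, against 12 in the fibroblast-like cluster. It took 33.9% of wild type cells with fatty acid (25.3 to 43.3) and 0.433% of mutant cells (0.0525 to 1.55), and 19.4% in EV, 28.6% in MiMac, 15.3% with let-7 and miR-452 and 20.1% with miR-122 and miR-200. With both unnamed clusters added to the class, a set chosen after seeing the data and called the wide class here, the shares were 88.7% of wild type and 71.9% of mutant cells (81.4 to 93.8 and 67.5 to 75.9). They were 95.8% in EV and 94.1% in MiMac. Wild type and mutant thus changed order with the unnamed clusters added. The dividing-like cluster was in neither set, though 17 cardiomyocyte markers were found in 50% or more of its cells. Values of cell cycle genes in the class and the wide class therefore leave out these cells by construction. Fibroblast-like cells made up 4.17% of EV cells (1.54 to 8.85), 11.3% of the wild type with fatty acid (6.16 to 18.6) and 18.8% of the mutant (15.4 to 22.7). Dividing-like cells were 9.31% of the mutant (6.82 to 12.3) and 12.3% of the mutant with SS-31 (10.1 to 14.6), against 0 of 115 wild type cells, which allows up to 3.16%.

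HADHA was the gene edited in the mutant cells. It stood at 34.2 CPM in the mutant and 128 in the wild type with fatty acid (log2 ratio -1.90, interval -2.14 to -1.66), and with SS-31 at 33.0 against 119 (-1.85, -2.06 to -1.65). In every library without the mutation it lay between 119 and 134 CPM. The edit was placed in exon 1, and 3' reads elsewhere in the transcript do not check the edit itself. CDKN1A, the p21 gene, was at 1369 CPM in the wild type and 9.63 in the mutant (-7.15, -7.50 to -6.83). MEG3, an imprinted non-coding RNA, was at 245 CPM in the wild type and 0 in the mutant, at least 653-fold lower. PLCG2, a phospholipase (160 and 8.01 CPM, -4.32), and BBC3, an apoptosis gene (-3.02), were lower as well. KRT7 (-4.85) drew 55.1% of its wild type UMIs from 1 cell. NCCRP1 (-3.32) and SNHG23 (-3.31) were lower, and MTRNR2L6 and MTRNR2L3 (-3.53 and -3.25) are near-identical copies of a mitochondrial gene and remain uncertain. TOP2A, the topoisomerase of dividing cells, was at 4.71 CPM in the wild type and 112 in the mutant (4.57, 3.72 to 5.58). A2M, a protease inhibitor, had 25.8 CPM in the mutant (4.91, 3.04 to 7.97). CENPF (5.69, 4.13 to 7.97), DEPDC1 (4.85), CCNA2 (4.98, 3.11 to 8.03), ACTG2 (5.90) and NPR3 (5.84, 3.35 to 11.15) were higher. CPB1 was at 86.1 CPM against 0, at least 67.0-fold higher, with 61.3% of its UMIs from 1 cell. Within the cardiomyocyte class the log2 ratios of HADHA, CDKN1A and BBC3 were -2.17, -7.65 and -3.72, and that of TOP2A 3.53. MEG3, with 0 UMIs in the mutant, was at -7.51 or lower there, a bound set by the floor. In the class NPR3 was at 0.02, CCNA2 at -0.72, CENPF at 1.36, DEPDC1 at 1.73 and ACTG2 at 1.5. CPB1, with 0 UMIs in the wild type, was at 0.20 or higher in the class and 1.21 or higher in the wide class, bounds set by the floor. NPR3, CCNA2 and CENPF had few wild type UMIs, as their wide intervals show, so their values in these sets may be set by the floor too. In the wide class TOP2A was at 1.96, NPR3 at 2.62, CCNA2 at 0.88, CENPF at 2.41 and ACTG2 at 2.52.

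Of 44 cell cycle genes on the minimum, 36 had intervals above 0 and 3 below, with a median log2 ratio of 2.37 (percentile 100 of random lists; 1.40 in the class). Of 25 genes of the cell cycle inhibitor list 16 were below 0 and 5 above (median -1.51, percentile 0; -1.45 in the class). The cholesterol synthesis list had a median of -0.66 (percentile 0), with CYP51A1 at 23.4 against 77.1 CPM (-1.72) and ACAT2 at -1.18 (-2.25 in the class). Fibroblast markers were at 0.80 (percentile 100; -0.59 in the class and -1.28 in the wide class). Oxidative phosphorylation genes had a median of -0.32 (percentile 0.46; -0.50 in the class), with UQCRQ at -0.88 and ATP5J at -0.83. Interferon genes had a median of 1.11 (percentile 100), with BST2 at 3.02 (1.89 in the class) and IFI6 at 2.15 (68.5 and 303 CPM). TRIB3 (2.33; 4.35 in the class) and ASNS (2.13), targets of the amino acid stress factor ATF4, were higher in the unfolded protein list (0.15, percentile 99.7; 0.56 in the class). Sarcomere genes were at -0.35 (percentile 1.06; -0.16 in the class and -0.03 in the wide class), with DES at -2.07 (-0.81 in the class and -1.70 in the wide class) and creatine kinase CKM at 1.42. Fetal genes were at -0.53 (percentile 0.09), with NPPB at -2.26 (-0.34 in the class and -1.92 in the wide class) and MYH6 at -1.65. The let-7 target list was at 0.16 (percentile 100; 0.04 in the wide class), with CCND1 at -1.55 (-2.14 in the wide class) and COL3A1 at 1.62 (0.52 in the class). CASQ2 was at -1.90 (-0.56 in the class and -1.51 in the wide class), and HEY2, a ventricular transcription factor, at 1.93 (1.26 in the class). TXNIP (1.51) was higher and FABP3, a fatty acid carrier, lower (-0.63). In the cardiolipin list, at percentile 38.1, LCLAT1, which remodels cardiolipin, was at 0.84 (1.36 in the class) and TRIAP1 at -1.03 (-1.61 in the class). The beta-oxidation list was at -0.23 (percentile 12.3), with ACADS at -0.95. Scaling by TMM moved the median of all genes from -0.09 to 0.05, and all these values are against the library totals.

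With SS-31 in both genotypes the mutant library was also low in CDKN1A (1387 and 10.8 CPM, -7.01), MEG3 (222 and 0 CPM, at least 819-fold lower), EDA2R, a receptor of the TNF receptor family (-7.90, -10.95 to -6.02), PLCG2 (-6.30), GDF15 (-5.34) and BBC3 (-3.13). CPB1 was at 147 CPM against 0, at least 188-fold higher, and A2M (5.63, 3.76 to 8.68), MGP (5.51), DEPDC1 (5.08), NUSAP1 (3.83), CDK1 (3.69), TNC (3.79) and BST2 (3.00) were higher. CYP51A1 was at -1.39, NQO1 at -1.91, HSPA1A at -2.41, CASQ2 at -2.22, HEY2 at 2.68 and CKM at 1.59. Within the class MGP was at 2.56, DEPDC1 at 2.74, NUSAP1 at 2.07, CDK1 at 1.80, TNC at 1.03, EDA2R at -6.28, CASQ2 at -1.07 and HEY2 at 1.85. CPB1, with 0 UMIs in the wild type, was at 0.92 or higher there, and MEG3, with 0 in the mutant, at -7.47 or lower. Both are bounds set by the floor, and EDA2R rests on few mutant UMIs, as its wide interval shows. NQO1 was at -0.36 among cells of 50000 UMIs or fewer, a limit added after seeing the data. BST2 was at 4.72 and CASQ2 at -1.88 in the wide class. HOPX was at -0.90 with SS-31 and at -0.09 (-0.39 to 0.22) without. List medians were 2.37 for the cell cycle (1.03 in the class), -1.42 for cell cycle inhibitors, -0.82 for cholesterol synthesis, 1.25 for interferon, -0.25 for oxidative phosphorylation and 0.90 for fibroblast markers (-0.04 in the class). Genes with a log2 ratio above 1 or below -1 numbered 149 and 264 of 7043 without SS-31, and 145 and 307 of 6921 with it.

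**Figure D3:**
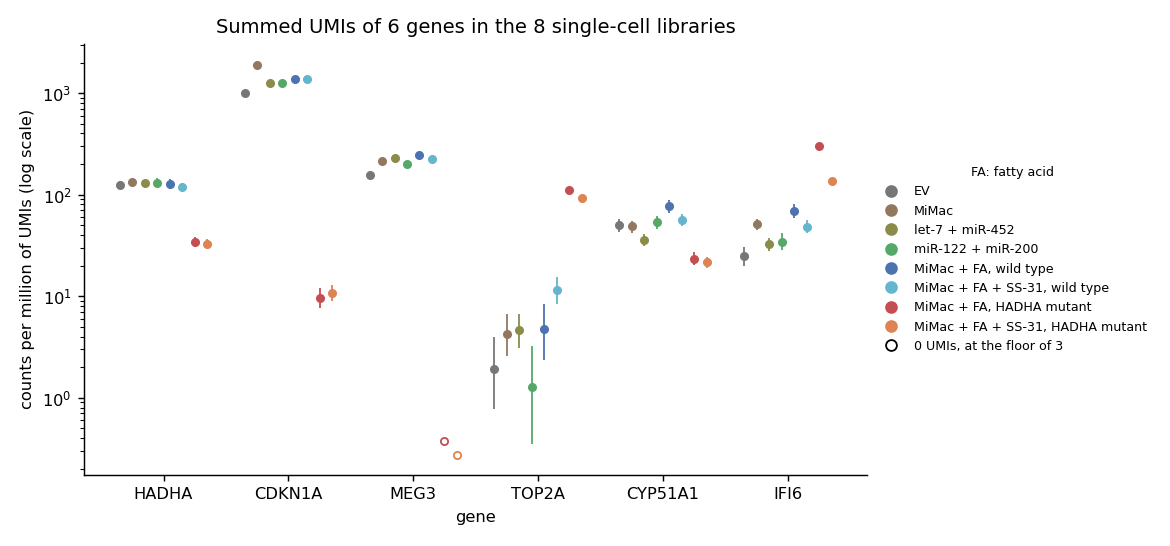
CPM (log axis) of 6 genes summed over the cells of the 8 single-cell libraries, with 95% Poisson intervals that cover counting error only; open points mark 0 UMIs, drawn at the floor of 3 counts. HADHA lies between 119 and 134 CPM in the 6 libraries without the mutation and at 34.2 and 33.0 in the mutant ones.

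The next comparison asks what SS-31 did in the mutant. HADHA did not differ beyond its interval (-0.05, -0.28 to 0.18), and 5 genes each way among 6583 passed a log2 ratio of 1. CYP1B1, a cytochrome P450, was higher (6.51 to 26.8 CPM, 2.04, 1.61 to 2.5), as were POSTN (0.97), RDH10 (0.82) and SPOCK2 (1.10). CXCL14 (1.28), HBD (1.21), MGP (1.08) and PLAC9 (0.79) were higher over all cells, but at -0.24, -0.68, -0.17 and -0.41 within the cardiomyocyte class (mostly cluster 5 in both libraries). SPOCK2 and LYPD1 were at 0.17 and -0.16 there, RDH10 at 0.35 and POSTN at 1.83. IFI6 was lower (303 to 135 CPM, -1.17, -1.26 to -1.07), with HLA-B at -0.78, NME2 at -1.23, ARF5 at -1.22, ZNF90 at -0.97, LAD1 at -0.92, HES1 at -0.90 (-0.44 in the class), LYPD1 at -0.88 and the uncertain MTRNR2L8 at -1.12. ASNS (-0.78), TRIB3 (-0.69), ESRRA (-0.63) and ACTA1 (-0.73) were lower, and HOPX was at -0.21. List medians stayed small, at -0.21 for interferon (percentile 0.04; 0.09 in the class), -0.15 for fetal genes, -0.14 for ion channels, 0.17 for fibroblast markers (0.31 in the class), 0.09 for cardiolipin genes (percentile 95.3; 0.15 in the class) and 0.04 for oxidative phosphorylation (percentile 91.8; 0.10 in the class).

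In wild type cells SS-31 went with higher LGALS1, a galectin (79.2 to 307 CPM, 1.96), OLR1 (2.11), SPON2 (2.00) and SLC7A11 (1.79), and with lower CSRP1 (-2.20), MTA2 (-1.63), EIF5AL1 (-1.63), TGFBR1 (-1.44) and NPY (-2.77, with 71.4% of its UMIs from 1 cell). Within the class OLR1 and SPON2 were at -0.58 and -0.16, LGALS1 at 0.86, CSRP1 at -1.17, EIF5AL1 at -0.75 and SLC7A11 at 2.42. In the wide class MTA2 was at -0.72, TGFBR1 at -0.69 and SPON2 at 1.02. NQO1 (1.44; -0.58 in the class) and MT2A (1.32; 0.42 in the class) lead the oxidative stress list (median 0.18, percentile 100; -0.05 in the class). Among cells of 50000 UMIs or fewer NQO1, MT2A and SLC7A11 were at -0.28, -0.19 and -0.40. ACTA1 was at 0.66 (-0.26 in the class and 0.69 in the wide class), POSTN at -0.87 (-1.84 in the class), HADHA at -0.10 and HOPX at 0.60 (0.03 in the class and 0.67 in the wide class). Sarcomere genes were at -0.12 (percentile 0.19), carriers at -0.29 (percentile 0.03; -0.11 in the class), oxidative phosphorylation at 0.00 (percentile 56.8; -0.12 in the class) and fibroblast markers at 0.27 (percentile 100; -0.06 in the class).

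Fatty acid medium was compared with glucose medium in MiMac cells. CPT1A, which admits long-chain fatty acids to mitochondria, went from 12.2 to 27.4 CPM (1.17, 0.63 to 1.72), and ETFDH was at 0.66, while the beta-oxidation list as a whole stayed near 0 (0.00, percentile 29.7; 0.12 in the class). NPY (5.33), PODXL (2.07), ACTG2 (-4.64), CCDC146 (-1.84; 0.98 in the class) and GGH (-1.67) each drew 61.7% or more of the UMIs from 1 cell. Within the class NPY was at 6.56, ACTG2 at -1.27 and GGH at -0.61, and in the wide class PODXL at 1.36. TNFRSF19 (1.98; 1.30 in the class) and COL8A1 (1.95; 3.98 in the class and 0.53 in the wide class) were higher, and DHRS3, a retinal reductase (75.2 to 17.1 CPM, -2.13), PPARGC1A (-0.67; -1.18 in the class), FDXR (-1.16) and HEY2 (-1.30) lower. MYOZ2 was at 0.64 and HSPA8 at 0.66, HADHA at -0.07 and HOPX at -0.32 (-0.64 to 0.00; 0.09 in the class). Mitochondrially encoded transcripts (-0.20, percentile 0.01) and citrate cycle genes (-0.16, percentile 0.02; -0.07 in the class) were lower, and epicardial markers (1.87, 5 members; 0.57 in the wide class) higher.

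MiMac and its parts were also compared with EV in single cells. In MiMac PLCG2 (25.7 to 234 CPM, 3.18), TGFBI (3.46), the collagen crosslinker LOX (3.48), COL11A1 (2.79), FBN1 (2.77), POSTN (2.74) and LUM (2.66) were higher, as were MYL2 (112 to 341 CPM, 1.60), TAGLN (1.13), CDKN1A (1004 to 1911 CPM, 0.93) and HLA-C (1.58). SFTA1P (5.69, 4.12 to 7.98) and KRT7 (3.52) drew 56.4% or more of their UMIs from 1 cell. Within the class SFTA1P was at 2.13, LOX at 4.42, COL11A1 at 1.31, FBN1 at 1.18, POSTN at 2.13, LUM at 3.45, KRT7 at 4.13 and HLA-C at 0.57. In the wide class POSTN was at 0.56, LOX at 2.49 and TGFBI at 2.83. KCNIP2, a potassium channel subunit (27.4 to 9.23 CPM, -1.57), FBXL22 (-1.40), COX6A2 (-1.32), CACNA1G (-0.69) and IRX4 (-0.66) were lower. MTRNR2L11, MTRNR2L10, MTRNR2L3, METTL12 and the antisense NPPA-AS1 (-2.06, -1.99, -1.89, -1.71 and -1.53) are uncertain, and METTL12 was at -0.51 in the class. Fibroblast markers (1.62; 0.57 in the wide class) and matrix genes (0.44; 0.24 in the wide class) were at percentile 100 and cholesterol synthesis at 0.40, while sarcomere genes were at -0.11 (percentile 0.53; -0.04 in the class and -0.01 in the wide class). Let-7 targets were at 0.03 (percentile 27.2; -0.09 in the class and 0.08 in the wide class) and the cell cycle at 0.04 (percentile 43.5; -0.26 in the class and -0.07 in the wide class). All 13 mitochondrially encoded transcripts had intervals below 0, with a median of -0.30 (percentile 0.01; -0.26 in the class). HADHA was at 0.12 and HOPX at -0.16.

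With let-7 and miR-452, LOX (2.62), MYL2 (1.95) and FHL2 (0.87) were higher, DHRS9 (2.85) and COL1A2 (2.21) drew 57.1% or more of their UMIs from 1 cell, and ACTG2 (-3.17) drew 65.8% of the EV UMIs from 1. MTRNR2L11 (-2.46), MTRNR2L10 (-1.84) and NPPA-AS1 (-2.33) are uncertain as before. ACTA2 was at -1.31 over all cells and 0.29 in the class. There DHRS9 was at 2.17 and ACTG2 at -0.62, and in the wide class LOX at 1.00 and COL1A2 at 0.83. The let-7 targets were at -0.14 (percentile 2.82), oxidative phosphorylation at 0.08 (percentile 99.9) and sarcomere genes at 0.06 (percentile 91.5; -0.01 in the class). Fibroblast markers were at 0.94 (percentile 100; -0.18 in the wide class) and matrix genes at 0.19 (percentile 100; -0.01 in the class and 0.00 in the wide class). HADHA was at 0.08 and HOPX at -0.16. With miR-122 and miR-200, CCL2 (7.68, 5.18 to 12.99), SPINK1 (7.31) and CYP1B1 (6.32, 4.43 to 9.38) drew at least 85.0% of their UMIs from 1 cell, and SFTA1P was at 5.90 (4.33 to 8.19; 2.80 in the class). CCL2 was at 1.93, SPINK1 at 4.97 and CYP1B1 at 0.76 in the class. FN1 (2.03; 1.17 in the class, 0.54 in the wide class and 0.64 among cells of 50000 UMIs or fewer) and NPPB (0.93; 0.42 in the wide class) were higher, and CDKN2A (2.09; 1.15 in the class and 0.91 in the wide class) drew 40.9% of its UMIs from 1 cell. ACTA1 (-1.55; -0.35 in the class) and DES (-1.05; 0.42 in the class) were lower, and NPPA-AS1 (-1.28) and METTL12 (-1.12) are uncertain. HADHA was at 0.08 and HOPX at -0.72 (-0.13 in the class, and 0.04 with each cell weighted equally). Endoderm markers were at 3.19 (2 members; 2.04 in the class), hypoxia genes at 0.38 (0.20 in the wide class), matrix genes at 0.54 (0.08 in the wide class), fibroblast markers at 1.32 (-0.06 in the wide class), mitochondrially encoded transcripts at -0.28 (percentile 0; -0.13 in the wide class) and sarcomere genes at -0.09 (-0.01 in the wide class and 0.04 among cells of 50000 UMIs or fewer).

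The bulk MiMac calls were looked up in the single cells, in separate libraries. Of the 385 genes called over 6 libraries 329 were measured, and 252 (76.6%) had the same sign in MiMac against EV single cells, where random genes gave 58.1% (95% range 52.9 to 63.5). Within the cardiomyocyte class 223 of 304 (73.4%) did, against 56.2% (50.7 to 61.8). The random genes were drawn singly, and genes expressed together are not independent, so these ranges do not measure the spread between libraries. TAGLN, CDKN1A and HLA-C were higher, and KCNIP2, CACNA1G and IRX4 lower, in both. The lists called in bulk did not all carry over. The cell cycle and let-7 lists, called down, had slightly positive medians over all cells, and the sarcomere list, called up, a negative one. Matrix genes, called up, and mitochondrially encoded transcripts, called down, kept their direction. The 11-library fit made no calls to look up, and this use of the 6-library calls was chosen after seeing the data.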

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

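The tests of the cell cycle inhibitor list, of the genes switched on or off, of the code series and of the splits were chosen only after the results were seen.

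Among 61 measures looked at in the 8 EV libraries, 8 had a library far from the others, where chance marks about 1 in 20 groups. EV 6, the library with the fewest counts and the only EV library of series C, stood highest for NRAP (18.7 CPM; next 5.15), NUPR1 (34.6), HLA-C (369), KRT8 (1680), CNN1 (1790), KCNIP2 (379) and HSPB1 (6270). EV 1 stood highest for MGAT4C (27.2 CPM; next 11.8). With SS-31, ACTA1, HOPX and POSTN lay in opposite directions in mutant and wild type cells, with a difference of log2 ratios (mutant minus wild type) of -1.39, -0.81 and 1.84. Within the cardiomyocyte class ACTA1 was lower in both (-0.26 in wild type and -0.68 in mutant cells), HOPX was at 0.03 and -0.28, and POSTN at -1.84 and 1.83. With the unnamed clusters added ACTA1 (0.69 and -0.58) and HOPX (0.67 and -0.17) lay in opposite directions again. Each rests on 1 library per condition, and the difference was not tested.

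Low genes of the cell cycle inhibitor list in both HADHA mutant libraries are the first pattern weighed. Its members CDKN1A, MDM2 and BBC3 were low, and EDA2R, which is not in the list, was low as well. A different share of cells outside the cardiomyocyte class is argued against by the list median within it, -1.45 without SS-31 and -1.63 with it (-1.61 and -1.38 with the unnamed clusters added). A different mix within the class cannot be judged this way, since wild type cells lay mostly in cluster 1 and mutant cells in cluster 5. CDKN1A and ZMAT3, members of the list, were among the top genes of cluster 1, so the clusters partly follow the list itself. Scaling of the totals is argued against by the median with TMM factors, -1.37 and -1.31. CDKN1A was also under 100 CPM in 8 of 20 bulk libraries, none of which a label calls HADHA mutant, so a difference between the lines other than HADHA may account for it. With 1 library per genotype and medium, and no label that gives its line, this and the HADHA genotype, the untested biological explanation, cannot be told apart.

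The second pattern is the set of genes switched off in the libraries labelled HOPX_OE, where CAT, H19, NPPB, SLC5A1, ANKRD1 and MFAP5 lay at least 4-fold under every other bulk library. A lower share of cardiomyocytes is argued against as the whole cause, since the 19 cardiomyocyte markers had a median log2 fold change of -1.01, with 17 lower. In all, 31 genes were switched on or off in this pair, against 3 in the negative controls, DLL1 and YPEL3-DT among them, and 0 in the other pairs of series D, but this count holds the genes of the pattern itself. Another clone or line behind the libraries labelled HOPX_OE therefore stays open, as do a mix-up of samples and raised HOPX, the biological explanation the label gives. HOPX was lower in both pairs than in EV 7 and 8 (34.4 and 41.5 CPM). Exchanging the labels of the pairs would turn the sign of its log2 fold change (-0.38, edgeR adjusted p = 0.128), still without a call. A vector whose sequence was not counted would leave these reads unable to decide on an exchange.

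The third pattern is genes fully on in some code series and off in others. CHCHD2 lay between 85.7 and 96.5 CPM in series A and C and at 0.0977 or less in B and D, NLRP2 between 48.4 and 69.7 against 0.069, and MEG3, the other way, between 41.4 and 276 in B and D and at most 0.145 in A and C. In all, 7 genes part A and C from B and D and 0 part the series in either other way, but these genes are the pattern itself. Different stem cell lines behind the code series therefore stay open, beside any other difference between the series. No biological explanation was tested, and the series split is not the study's treatment, though MiMac 1 and EV 6 lie on one side and MiMac 2 and 3 on the other.

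For MiMac against EV over 11 libraries the splits decide nothing. The real split called 0 genes, so each of the 99 splits called as many or more by construction. The highest other split, EV 1, EV 4 and EV 5 against the rest, called 9411, which points to a structure of the samples. Over the 6 libraries of series C and D the real split called 385 genes and the highest other 0. The real one was 1 of 10 splits, too few for a share under 0.05.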

How the results depend on the processing

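The settings that leave out EV 2 and 3 or EV 4 and 5, that use either pair alone as controls, that leave out cells over 50000 UMIs or the dividing-like cluster, that add the unnamed clusters to the cardiomyocyte class, and that carry the 6-library calls into the lists, the overlap and the single cells were chosen after the results were seen. Of 58 MiMac bulk genes named, taken here from the 11-library fit, 43 kept their direction under every setting run, as did 57 of 58 genes in the libraries labelled HOPX_OE, 28 of 28 genes of single bulk libraries and 146 of 167 single-cell ratios. Of the other single-cell ratios 16 turned as given below, and 5, of HOPX or HADHA, changed sign with an interval that held 0. For the changes below the cause was not tested, unless fewer libraries or genes entered by construction. Over the 11 libraries simulated 2-fold changes were recovered in 3% of cases, and over the 6 libraries in 96%.

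MiMac against EV had 0 calls over 11 libraries (edgeR; 410 at an unadjusted p under 0.05) and 0 without any 1 library, without a filter, with RLE factors, with all 20 libraries and without the series term. DESeq2 gave 9, the 6 shared libraries 385, series D alone 2406, the fit without EV 2 and 3 80 and without EV 4 and 5 730. The 5 list calls became 13 over 6 libraries, 0 with an estimated correlation, 0 with fry and 4 to 9 without 1 library. In the 6 libraries the overlap with the HOPX_OE calls was 80, against 0. The HOPX_OE count of 3290 became 159 with no filter, 257 over all 20 libraries and 1504 with a fold limit. It lay between 1322 and 6368 without 1 library, in fits where the lone library of an arm is assumed to vary like the other pair. Its 15 list calls became 0 with an estimated correlation, 5 with fry and 11 to 19 without 1 library. HADHA there lay between -0.127 and 0.136 without 1 library, and was -0.0136 without negative control 1.

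Replicate numbers share only a number here: same-numbered libraries correlated at 0.116 in the HOPX groups and at 0.0304, -0.0654 and 0.127 for MiMac. With a replicate block MiMac kept 0 calls and HOPX_OE had 5155, and its 15 list calls stayed 15. The block turned TFPI2 (-0.18), AFAP1L2 (-1.10), RGS4 (-1.02), TAGLN (-0.29), TRIB3 (-0.33), TNC (-4.17), STAT4 (-0.46), KLF6 (-0.28), ENO1 (-0.11), PGK1 (-0.020), TRDN (0.086), KCNIP2 (2.03), CACNA1G (0.030), PPP1R3A (0.37) and HADHA in the HOPX groups (-0.0058). Without the series term, AFAP1L2 (-0.24), RGS4 (-0.17), PSMB8 (-0.048), TAGLN (-0.088), TRIB3 (-0.13), TNC (-3.67), ENO1 (-0.35), PGK1 (-0.034) and KCNIP2 (0.54) turned, and the unfolded protein list pointed down (adjusted p = 0.588).

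Within the cardiomyocyte class these single-cell log2 ratios turned: ACTA2 with let-7 and miR-452 (0.29), METTL12 (0.063) and DES (0.42) with miR-122 and miR-200, CCDC146 in fatty acid (0.98), CCNA2 in the mutant (-0.72), OLR1 (-0.58), SPON2 (-0.16), ACTA1 (-0.26) and NQO1 (-0.58) with SS-31 in the wild type, and CXCL14 (-0.24), HBD (-0.68), MGP (-0.17) and PLAC9 (-0.41) with SS-31 in the mutant. CCNA2 had few wild type UMIs and the class leaves out the dividing-like cluster, so its turn may be set by the floor and by that choice of cells. HADHA in the mutant moved to -2.17, and the oxidative phosphorylation median with SS-31 to -0.12 in the wild type and 0.10 in the mutant. With the unnamed clusters added to the class CCDC146 (0.052), OLR1 (-0.30), NQO1 (-0.18), CXCL14 (-0.41), HBD (-0.67), MGP (-0.23) and PLAC9 (-0.41) turned, and oxidative phosphorylation with SS-31 in the mutant was 0.11. Among cells of 50000 UMIs or fewer METTL12 (0.011), DES (0.25), CCDC146 (0.65), SLC7A11 (-0.40), NQO1 (-0.28), MT2A (-0.19) and the sarcomere median with miR-122 and miR-200 (0.039) turned, and that with let-7 and miR-452 was -0.022. TMM factors gave 0.16 for the latter and 0.059 for oxidative phosphorylation with SS-31 in the wild type. Weighting each cell equally gave -0.040 for that sarcomere median, 0.044 for HOPX and 0.19 for DES with miR-122 and miR-200, and -0.024 for oxidative phosphorylation with SS-31 in the mutant. Single bulk sarcomere medians against all 8 EV libraries were 0.10 (miR-208b) and 0.32 (miR-122 knockout). Against EV 2 and 3 they were -0.50 (miR-378e), -0.53 (miR-205 knockout), 0.56 (miR-452) and 1.31 (miR-122 knockout), and against EV 4 and 5 -1.64, -1.90, -0.93 and -0.031.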

Other observations

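The bulk level of the cell cycle inhibitor CDKN1A differed widely between libraries of the same label. It lay at 43.4 and 44.4 CPM in EV 2 and 3, 16.7 with miR-378e, 17.8 with miR-205 knockout, 32.2 and 30.8 in the negative controls for HOPX and 9.08 and 8.22 in the libraries labelled HOPX_OE, and at 1409 CPM or more in each of the other bulk libraries. EDA2R lay at or below 2.25 CPM in the libraries just named and at 23.3 CPM or more elsewhere. DLK1, the imprinted partner of MEG3, lay between 208 and 383 CPM in EV 2 and 3, miR-378e and miR-205 knockout, and at 7.46 and 11.5 in EV 4 and 5. In the negative controls for HOPX it lay at 11.5 and 10.2 CPM, and in the libraries labelled HOPX_OE at 79.9 and 85.6. DLK1 was thus not high in every library with low CDKN1A. These values were looked up after the result was seen.

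Mitochondrial messenger RNA took 2.44 to 4.38% of counts in series B, 25.4 and 29.4% in series C and 8.16 to 18.9% in series D, so the share of counts left to nuclear genes differed between series. Within series D it was lower in the HOPX groups (8.16 to 9.06%) than in EV and MiMac (15.5 to 18.9%). In the single cells MEG3 was present in 6 libraries (158 to 245 CPM) and at 0 in both HADHA mutant libraries. CHCHD2 was at or under 0.636 CPM in all 8.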
